A study of Danio rerio with 4 samples.

How the data were processed

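RNA was sequenced from 4 libraries of FACS-sorted adult zebrafish ventricular cardiomyocytes, 2 per group. The groups were myl7:EGFP+ cells (7000 cells per sample, per the series' design text) and tp1:EGFP+/myl7:DsRed2-NLS+ cells (2000 cells). The tp1 element is a Notch-responsive reporter and myl7 is a cardiomyocyte promoter, so the second group holds cardiomyocytes with reporter activity. Per the labels' protocols, full-length cDNA was made from low nanogram amounts of total RNA with a SMART-Seq v4 kit, sheared by ultrasound and turned into libraries with 2 kits, and the labels do not say which kit served which library. The column kit for RNA extraction is named differently in the labels' protocols and in the design text.

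Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.6.1d, featureCounts, Subread 1.6.5 and DESeq2 1.26.0 were used, with the builds danRer11 and GRCz11. The roles and settings of these tools, and the treatment of strand, duplicates and multi-mapping reads, are not given in the sources used here. The values deposited by the authors are a score, namely normalized read counts rounded to whole numbers, for 18105 Ensembl genes on 25 chromosomes with 1 column per library. They are not raw counts. In both replicate 2 columns, the values were rounded multiples of 3.109 (myl7:EGFP+) and 2.98 (tp1:EGFP+), the value of 1 read. In the replicate 1 columns the best steps were below 1 (0.266 and 0.352), so rounding hides single reads, and for myl7:EGFP+ a step of 0.174 gave nearly the same misfit (222.1 against 221.3) and would put the depth at 8933464 reads. Whole reads were therefore not recovered and no count model was fitted. The step finder was tested on simulated data and recovered 4 of 4 steps. These steps put the depth at about 5828213 and 685388 reads for myl7:EGFP+ replicates 1 and 2, and at 4712006 and 685039 reads for tp1:EGFP+ replicates 1 and 2. The medians of the ratios of each column to the geometric mean lay between 0.993 and 1.02, so the columns were taken as already scaled to one another.

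Values were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with the trend option, over 9921 genes with a mean of at least 10 over the 4 libraries. The Benjamini-Hochberg adjusted p threshold was 0.05 and differences are tp1:EGFP+ minus myl7:EGFP+. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. A total of 27 gene lists were fixed before the data were examined. Lists with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The same lists were tested with fry, which asks whether the genes of a list move one way on balance and makes no comparison with other genes. Gene names came from the deposited table, which was matched to a reference name table by Ensembl ID for 17165 of the 18105 genes. Correlations and intervals used Python 3.11.15 with scipy 1.17.1 and numpy 2.4.6, tables pandas 2.3.3, and plots matplotlib 3.10.9.

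The genes named were set by rule before the data were examined. They were the 10 largest rises and 10 largest falls among called genes with separated groups, a mean of at least 100 in the higher group and a symbol that is not a clone name. Up to 4 called members of each list with the smallest p (or the 2 most abundant where none was called) and 31 symbols of interest were added, 25 of them tested. This gave 120 genes. A few further genes are named where a count would otherwise be unclear, and the text says that they were chosen after their values were seen.

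The test was run on simulated data in which each library varied independently, with the spread observed between the 2 libraries of a group. With 200 of 9921 genes changed, 0 of 50 genes were recovered at 2-fold, 0 of 50 at 4-fold, 3 of 50 at 8-fold and 13 of 50 at 32-fold, and 0 of 9721 unchanged genes were called. With 3400 genes changed, a setting added afterwards because the observed share of called genes was of that order, the test recovered 30.2% at 2-fold, 60.1% at 4-fold, 78.6% at 8-fold and 92.6% at 32-fold, and called 107 of 6521 unchanged genes. Power therefore depended on how many genes changed, and a gene that was not called can still differ by a moderate fold. Differences shared by both libraries of a group, or by both groups at a replicate number, were not simulated. The counts of unchanged genes called therefore leave out calls from differences between sorts or pools.

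The alternatives, also fixed beforehand, were other pseudocounts (0.5 and 10), no filter or a mean of at least 50, other scalings (trimmed mean of M values, re-implemented with trims of 30% and 5%, quantile, and a common total), no trend, a robust fit, the replicate number as a block, each library left out in turn, and a required change of 2-fold. With 2 libraries per group, an outlier test or regrouping of the samples was not possible. The labels do not state that the 2 libraries of a group came from separate animals or sorts, so p-values measure only the spread between these libraries, which may be technical. No library column was left out.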

Results

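The series measured gene expression by RNA-seq in adult zebrafish (Danio rerio) ventricular cardiomyocytes sorted on 2 reporter combinations, and its title puts it in the context of heterogeneity among cardiomyocytes. The myl7:EGFP+ group marks cardiomyocytes in general, and the tp1:EGFP+/myl7:DsRed2-NLS+ group (tp1:EGFP+ below) marks those with activity of a Notch-responsive reporter. Each group had 2 libraries. The normalized values summed to 1552636 and 2130733 in the myl7:EGFP+ replicates 1 and 2, and to 1660511 and 2041552 in the tp1:EGFP+ replicates. Genes with a value above 0 numbered 14281 and 12417 in myl7:EGFP+ and 12558 and 11516 in tp1:EGFP+. The estimated depth was 8.5 times greater in replicate 1 than in replicate 2 of myl7:EGFP+, or 13.0 times with a value per read that fitted almost as well, and 6.88 times greater in tp1:EGFP+. The 10 most abundant genes held 3.63% and 5.65% of the values in myl7:EGFP+ and 3.49% and 5.23% in tp1:EGFP+.

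Across genes, which are not independent replicates, Pearson's r of the log2(value + 1) values was 0.932 between the 2 myl7:EGFP+ libraries and 0.942 between the 2 tp1:EGFP+ libraries. Between groups, r was 0.503 to 0.568 over the 4 pairs of libraries.

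The comparison of tp1:EGFP+ with myl7:EGFP+ cardiomyocytes asked which genes differ between reporter-active cardiomyocytes and cardiomyocytes at large. By limma with Benjamini-Hochberg adjustment, 3382 of the 9921 tested genes (34.1%) passed the threshold, 1599 higher and 1783 lower in tp1:EGFP+. In these cells the Notch target hey2, the receptor notch3 and the ligand jag1b rose, whereas her9, a member of the Notch target list, and the ligand jag2b fell. Core sarcomere genes such as myl7 and tnnt2a did not pass the test, with wide SEs (1.27 and 1.34 on the log2 scale). By contrast actn1, tagln and tpm1 rose and the atrial myosin gene myh6 fell. Whether myh6 fell within ventricular cardiomyocytes was not tested. Markers of mural and smooth muscle cells were higher and endothelial markers lower as sets by camera at a preset correlation (adjusted p = 0.00623 for both), but not at an estimated one (adjusted p = 0.787 for both with an estimated correlation). The differences of all 3382 called genes had the same sign within replicate 1 and within replicate 2. Passing the test on the same values largely requires this, so it is not a separate check. At 2-fold or more, 1561 genes were higher and 1758 lower. Of the called genes, 233 of those higher were listed at 0 in both myl7:EGFP+ libraries, and 341 of those lower were listed at 0 in both tp1:EGFP+ libraries. Leaving out 1 library left 75 higher and 348 lower genes without myl7:EGFP+ replicate 1, and 69 and 365 without its replicate 2. The counts were 271 and 356 without tp1:EGFP+ replicate 1, and 264 and 137 without its replicate 2. Of the 110 genes named by rule that had a call, 95 lost it without at least 1 library.

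**Figure D1:**
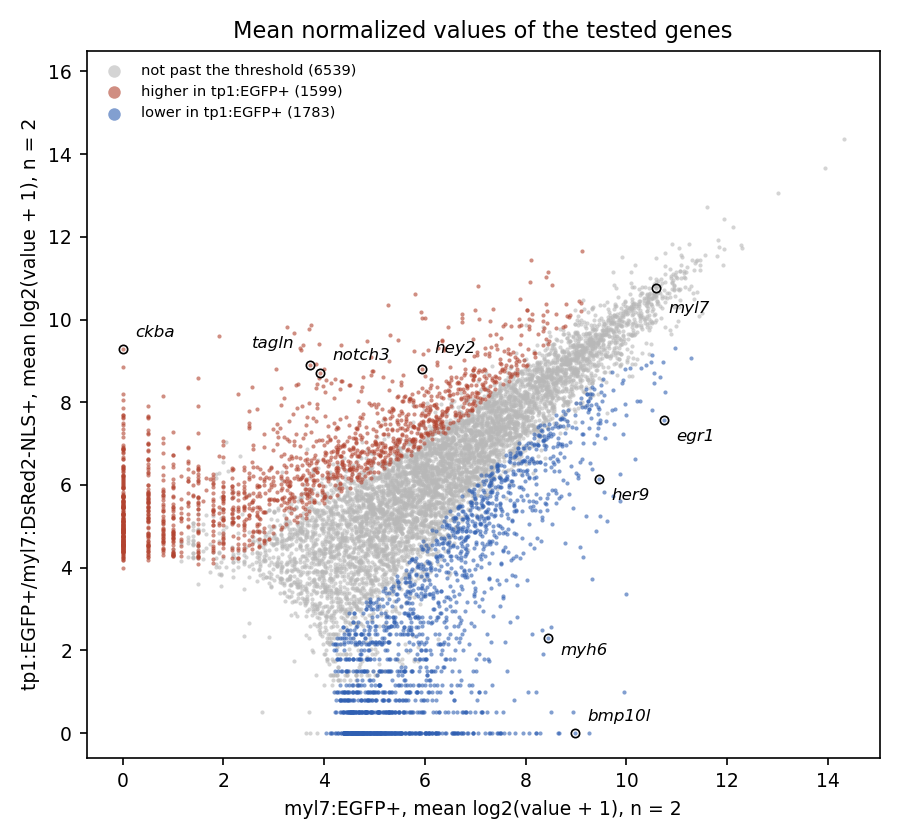
Each point is one of the 9921 tested genes, with the mean log2(value + 1) of the 2 myl7:EGFP+ libraries on the x axis and of the 2 tp1:EGFP+ libraries on the y axis, coloured by its limma call. The 1599 genes higher in tp1:EGFP+ lie above the diagonal and the 1783 lower genes below it, with a row of genes at 0 along each axis.

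The 10 largest rises were ckba, cdh1, syt13, cachd1, etnppl, ehd2b, cdh26.1, tfa, ccn1l1 and kalrnb. All except ehd2b were listed at 0 in both myl7:EGFP+ libraries. Among them, the creatine kinase gene ckba had values of 543 and 715 in the tp1:EGFP+ replicates, and cdh1, which encodes E-cadherin, had 381 and 551. The synaptotagmin gene syt13 had 307 and 277. For ehd2b the values were 13 and 0 in myl7:EGFP+ against 971 and 626 in tp1:EGFP+. The myl7:EGFP+ group marks cardiomyocytes in general, so reporter-active cells within it would carry transcripts of these 10 genes. The share of such cells in that group was not measured. If expression alone caused these differences, that share would have to be small, since ckba was at 0 in both myl7:EGFP+ libraries. Why the values there were at or near 0 was not tested. The 10 largest falls were bmp10l, nhsl1a, scn3b, casq1b, cavin1a, steap4, scn5lab, igf1rb, kcnq1.1 and gja5b, of which all except nhsl1a and kcnq1.1 were listed at 0 in both tp1:EGFP+ libraries. The ligand gene bmp10l had 509 and 501 in myl7:EGFP+, and nhsl1a fell from 1148 and 846 to 3 and 0. The sodium channel genes scn5lab and scn3b had 398 and 215, and 445 and 370, in myl7:EGFP+, the potassium channel gene kcnq1.1 fell from 396 and 330 to 1 and 0, and the connexin gene gja5b had 368 and 131.

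Members of the Notch target list went both ways, and whether each of them responds to Notch in these cells was not tested. Of 12 tested, 4 rose, 2 fell and 6 did not pass, and the counts were also 4 and 2 adjusted over the list alone. The gene hey2 (ENSDARG00000013441, chromosome 20, 39588897 to 39596338, GRCz11), a Hairy-related transcriptional repressor, rose from 61.0 ± 9.90 to 442.5 ± 10.6 (SD, n = 2). Its log2 difference was 2.85 ± 0.25 (SE), with a limma adjusted p of 0.00221, and was 2.99 within replicate 1 and 2.71 within replicate 2. The repressor gene her15.1 rose from 31 and 34 to 89 and 128 and the feedback gene nrarpa from 30 and 40 to 87 and 86 (limma adjusted p = 0.0211 and 0.0406). In the opposite direction, her9 (chromosome 23) fell from 714 ± 216 to 70.0 ± 14.1 (SD, n = 2; log2 -3.31 ± 0.33 SE, limma adjusted p = 0.00291). The related gene nrarpb fell from 31 and 28 to 1 and 0. The values of her6 were 635 and 1411 against 576 and 802, those of her4.1 were 253 and 973 against 320 and 593, and neither passed. The target hey1 was under the filter, at 0 and 0 against 4 and 3. By camera the list did not differ from other genes (adjusted p = 0.839), and its median (-0.15) and mean (-0.20) were of the opposite sign to the test. The her4 and her15 genes are near-identical copies, and how the authors' counting split their reads is unknown.

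Of the 18 tested Notch receptors, ligands and modulators, 4 rose and 9 fell, with 5 and 9 adjusted over the list alone (camera adjusted p = 0.339). The receptor notch3 (ENSDARG00000052139, chromosome 3, 53526025 to 53559581) rose from 15.5 ± 9.19 to 422 ± 73.5 (SD, n = 2; log2 4.79 ± 0.48 SE, limma adjusted p = 0.00307). It is also a member of the mural list, 8 of whose 10 tested members rose. The ligand jag1b rose by a log2 of 1.55 ± 0.29 (limma adjusted p = 0.0161). By contrast, jag2b and notch2 fell, with log2 differences of -2.19 and -1.61 (limma adjusted p = 0.00391 and 0.0217). The receptor gene notch1a fell from 35 and 40 to 1 and 0 and the ligand gene dll4 from 48 and 47 to 4 and 0, and both are known from endothelium, of whose 22 tested markers 12 fell and 2 rose (adjusted p = 0.787 for that list by camera with an estimated correlation). The gene rbpja, which encodes the DNA-binding effector of the pathway, had 99 and 96 in myl7:EGFP+ and was listed at 0 in both tp1:EGFP+ libraries, as was psen2 (31 and 25 in myl7:EGFP+). The gene notch1b had 59 and 37 against 78 and 36 and did not pass. The genes hey2, jag1b, jag2b, notch2, her9, her15.1 and nrarpa lost their calls whichever library was left out, although their log2 differences kept their sign and at least 80.7% of their size. Such fits leave 1 library in a group and lower the number of calls over all genes, so this loss is not particular to these genes. For hey2 the log2 difference was then between 2.68 and 3.01.

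**Figure D2:**
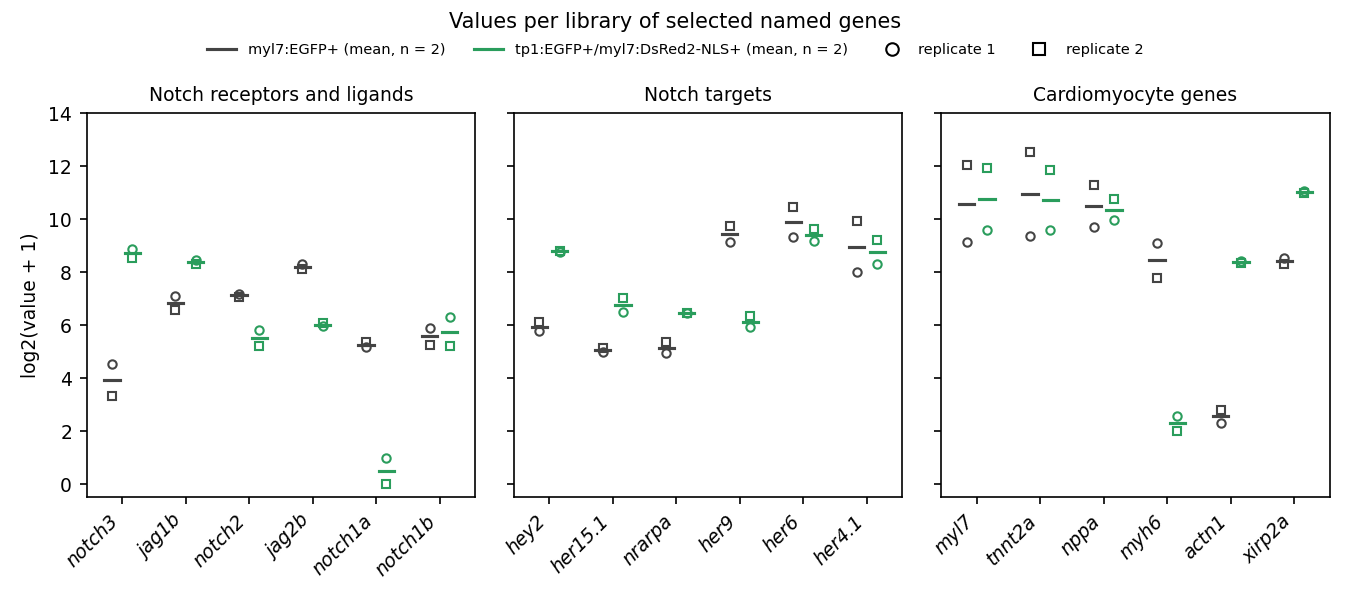
Values per library as log2(value + 1) for selected Notch and cardiomyocyte genes, with circles for replicate 1, squares for replicate 2 and a bar at the mean of each group (n = 2). For hey2 and notch3 both tp1:EGFP+ libraries lie above both myl7:EGFP+ libraries, while for myl7 the replicates of one group lie farther apart (565 and 4206) than the groups do.

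Contractile and identity genes of cardiomyocytes were mostly not called. Of 36 tested, 0 rose and 4 fell, with 0 and 3 adjusted over the list alone (camera adjusted p = 0.647, median log2 0.02 and mean -0.36). The values of myl7, whose promoter drives a sorting reporter in each group, were 565 and 4206 in myl7:EGFP+ and 765 and 3916 in tp1:EGFP+, a log2 difference of 0.44 within replicate 1 and -0.10 within replicate 2. For tnnt2a, cardiac troponin T, these were 0.24 and -0.65. The SE of the log2 difference was 1.27 for myl7 and 1.34 for tnnt2a, so a moderate difference in either gene could hardly have passed. The 4 genes that fell were myh6, the troponin C gene tnnc1b, the sodium-calcium exchanger gene slc8a1a and the myomesin gene myom1b. The values of myh6 (ENSDARG00000090637, chromosome 20, 53577502 to 53583436) were 550 and 221 in myl7:EGFP+ and 5 and 3 in tp1:EGFP+ (log2 -6.16 ± 0.58 SE, limma adjusted p = 0.00261). For myom1b and slc8a1a the log2 differences were -1.64 and -1.85.

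Genes of immature or dedifferentiating cardiomyocytes included 8 that rose and 1 that fell among 18 tested, in both cases also adjusted over the list alone, and the list just missed the camera threshold (adjusted p = 0.0516). The actin cross-linker gene actn1 rose from 4 and 6 to 341 and 322 (log2 5.81 ± 0.38 SE, limma adjusted p = 0.00213), and the tropomyosin gene tpm1 from 10 and 9 to 117 and 131. The intercalated disc gene xirp2a rose from 367 and 314 to 2139 and 2047, a log2 difference of 2.62 ± 0.32 (limma adjusted p = 0.00509). By contrast fhl2b fell from 323 and 208 to 12 and 12. The natriuretic peptide gene nppa, at 832 and 2487 against 1000 and 1740, did not pass. In this list 2 genes are also in the mural list, tagln and, named after its values were seen, acta2.

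Among 15 cardiac transcription factors, 2 rose and 2 fell, with 0 and 1 adjusted over the list alone (camera adjusted p = 0.908, median log2 0.04 and mean -0.22). The genes gata5 and hand2 rose by log2 1.02 ± 0.26 and 1.23 ± 0.33, and tbx5a and foxp4 fell by 1.57 and 1.61 on the log2 scale (limma adjusted p = 0.0403, 0.0455, 0.0307 and 0.0103). All 3 tested atrial genes were called, 1 higher (sypl2b) and 2 lower (myh6 and smtnl1), as also adjusted over the list alone (camera adjusted p = 0.339). The values of smtnl1 were 167 and 190 in myl7:EGFP+ and it was listed at 0 in both tp1:EGFP+ libraries. The sorted cells are described as ventricular, and which cells gave the myh6 and smtnl1 values in myl7:EGFP+ was not tested. Their falls are therefore not shown to be a change within ventricular cardiomyocytes. Of 11 conduction and atrioventricular canal genes, 2 rose and 3 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.639). The canal genes bmp4 and has2 were listed at 0 in both myl7:EGFP+ libraries and had 103 and 60, and 48 and 21, in tp1:EGFP+.

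Mural and smooth muscle markers were higher in tp1:EGFP+, with 8 of 10 higher and 0 lower, also adjusted over the list alone. The camera adjusted p was 0.00623, and adjusted p = 0.787 with an estimated correlation. The smooth muscle myosin gene myh11a and the pericyte receptor gene pdgfrb were listed at 0 in both myl7:EGFP+ libraries and had 60 and 48, and 19 and 27, in tp1:EGFP+. The actin-binding gene tagln rose from 24 and 6 to 451 and 510 (log2 5.18 ± 0.65 SE, limma adjusted p = 0.00543). With genes of a mean of at least 50 alone, the list no longer passed (camera adjusted p = 0.124), whereas it passed without each library in turn (adjusted p 0.00752 to 0.00950).

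Endothelial and endocardial markers were lower in tp1:EGFP+, with 12 of 22 lower and 2 higher, and 14 and 3 adjusted over the list alone. The camera adjusted p was 0.00623, and adjusted p = 0.787 with an estimated correlation. The receptor gene kdrl fell from 190 and 118 to 25 and 21 (log2 -2.66 ± 0.38 SE, limma adjusted p = 0.00785), and cdh5, which encodes vascular endothelial cadherin, fell from 212 and 112 to 22 and 12. The genes tie1, erg and fli1a were listed at 0 in both tp1:EGFP+ libraries and had 53 and 56, 44 and 28, and 89 and 44 in myl7:EGFP+. The 2 genes higher in tp1:EGFP+ were cldn5b and, named here after its values were seen, pecam1. Both were listed at 0 in myl7:EGFP+ and had 29 and 27, and 19 and 30, in tp1:EGFP+.

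**Figure D3:**
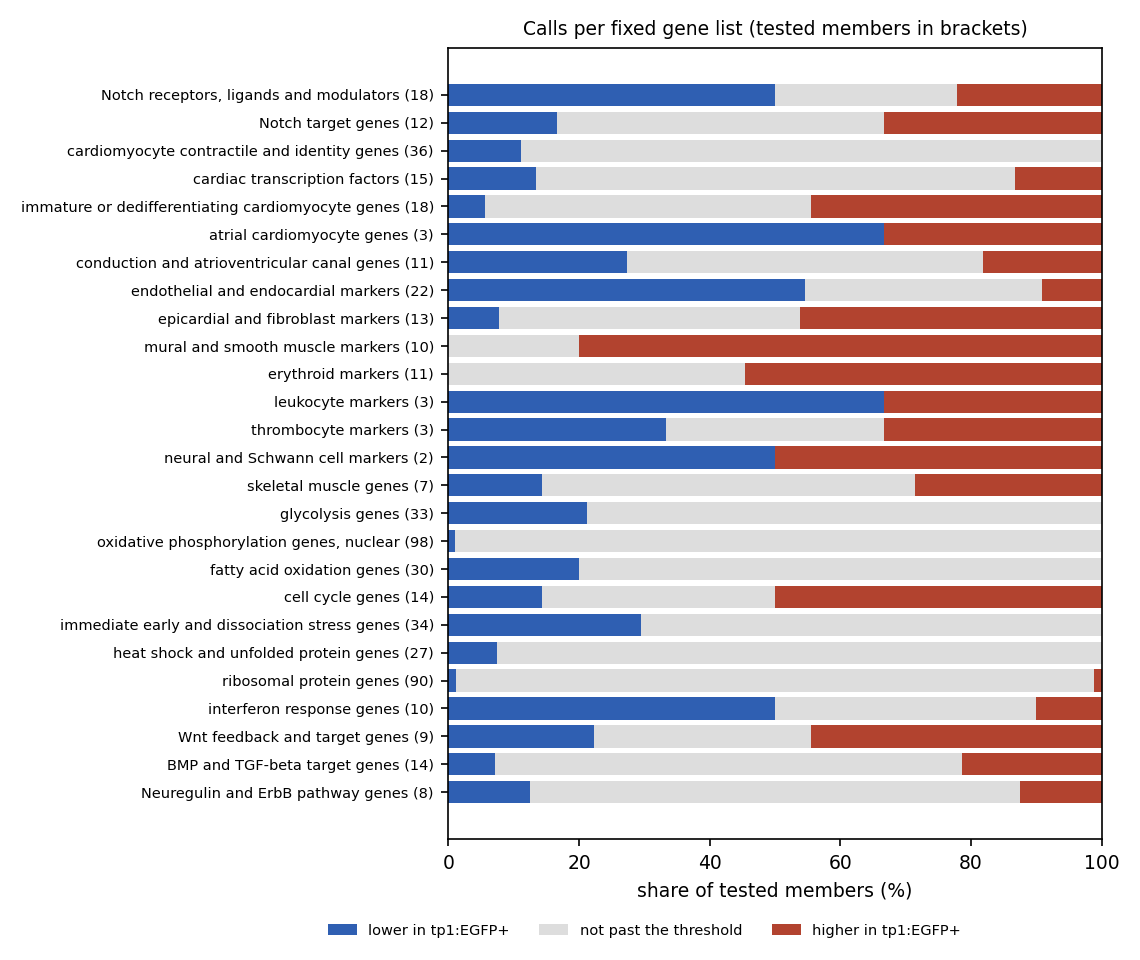
For each fixed list with a tested member, the bar shows the share of tested members lower in tp1:EGFP+, not past the limma threshold, and higher in tp1:EGFP+, with the number tested in brackets. The mural list is 8 of 10 higher, the endothelial list 12 of 22 lower, and the lists of oxidative phosphorylation and ribosomal protein genes are nearly all not called. Genes that are not called are not shown to be unchanged.

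No other list of cell type markers tested as a set passed the camera threshold. Among 11 erythroid markers, 6 rose and 0 fell, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0651). The globin gene hbba2 was listed at 0 in both myl7:EGFP+ libraries and had 41 and 86 in tp1:EGFP+, and globin copies can share reads. Of 13 epicardial and fibroblast markers, 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0683). The collagen gene col12a1a and the fibronectin gene fn1b were listed at 0 in myl7:EGFP+ and had 47 and 42, and 29 and 24, in tp1:EGFP+, whereas clu fell from 414 and 395 to 53 and 48, and col1a1a (15 and 9 against 27 and 27) did not pass. Of 3 leukocyte markers, 1 rose (cd79a) and 2 fell (cd74b and cxcr4b), and mpeg1.1 was listed at 0 in all 4 libraries. Of 3 thrombocyte markers, 1 rose (thbs1b, 1 and 0 against 134 and 167) and 1 fell (f5). Of 7 skeletal muscle genes, 2 rose and 1 fell, and mybpc1 rose from 16 and 12 to 750 and 608 (log2 5.51 ± 0.29 SE, limma adjusted p = 0.00213). These counts were the same adjusted over the list alone, with camera adjusted p of 0.555, 0.839 and 0.676. The skeletal list had a median of -0.33 and a mean of 1.11. Of 2 neural and Schwann cell markers, snap25b rose and syt1a, at 28 and 31 in myl7:EGFP+, was listed at 0 in both tp1:EGFP+ libraries, and the list was too small for a set test.

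Called genes of energy metabolism were lower. Of 30 fatty acid oxidation genes, 0 rose and 6 fell, with 0 and 5 adjusted over the list alone (camera adjusted p = 0.0683). Lipoprotein lipase, lpl, fell from 325 and 311 to 33 and 36 (log2 -3.17 ± 0.25 SE, limma adjusted p = 0.00213), the dehydrogenase gene acads from 319 and 274 to 56 and 39, and the nuclear receptor gene esrra from 598 and 628 to 171 and 158. Of 33 glycolysis genes, 0 rose and 7 fell, with 0 and 6 adjusted over the list alone (camera adjusted p = 0.192). The regulator gene pfkfb3 fell from 353 and 379 to 38 and 27 and the glucose transporter gene slc2a1a from 287 and 305 to 60 and 48. Among 98 nuclear oxidative phosphorylation genes, 0 rose and 1 fell (ndufaf2), with 0 called adjusted over the list alone (camera adjusted p = 0.908). The SE of the log2 difference was 1.05 for atp5po, named after its values were seen. A moderate difference in such a gene could hardly have passed. No mitochondrially encoded gene was analysed here.

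Cell cycle genes included 7 that rose and 2 that fell among 14 tested, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.0683). The replication genes mcm2 and tyms were listed at 0 in both myl7:EGFP+ libraries and had 30 and 36, and 27 and 18, in tp1:EGFP+. The cyclin gene ccnd2a rose from 75 and 68 to 257 and 232 (log2 1.76 ± 0.24 SE, limma adjusted p = 0.00682). The mitotic kinesin gene kif20a had 26 and 25 in myl7:EGFP+ and was listed at 0 in tp1:EGFP+. Of 34 immediate early and dissociation stress genes, 0 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.130). The transcription factor gene egr1 fell from 1452 and 2002 to 185 and 191 (log2 -3.17 ± 0.30 SE, limma adjusted p = 0.00268) and socs3b from 853 and 871 to 223 and 140, while fosab, at 586 and 3277 against 755 and 2602, did not pass. Of 27 heat shock and unfolded protein genes, 0 rose and 2 fell (calr and pdia4), with 0 and 1 adjusted over the list alone (camera adjusted p = 0.891, median log2 0.01 and mean -0.04). Of 10 interferon response genes, 1 rose and 5 fell, with 1 and 7 adjusted over the list alone (camera adjusted p = 0.0683), among them irf9 and stat2 with log2 differences of -1.81 and -2.36.

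Signalling lists went both ways. Of 9 Wnt feedback and target genes, 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.339). The secreted inhibitor gene wif1 rose from 1 and 0 to 123 and 107, and lef1 fell from 18 and 22 to 4 and 3. Of 14 BMP and TGF-beta targets, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.639), with log2 rises of 1.83 for id3 and 1.41 for smad9 and a fall of smad6b from 29 and 19 to 1 and 0. Of 8 Neuregulin and ErbB pathway genes, hbegfa rose (log2 1.85 ± 0.45 SE, limma adjusted p = 0.0347) and bmp10l, which encodes a BMP-family ligand and no ErbB receptor or ligand, fell, the same counts adjusted over the list alone (camera adjusted p = 0.639). Of 90 genes taken as ribosomal protein genes by the start of their symbols, 1 rose and 1 fell, with 0 and 1 adjusted over the list alone (camera adjusted p = 0.676). Both called genes, rps6kc1 and rps6ka1, are kinase genes with a similar symbol.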

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

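Counts of called genes stayed within 1.5 times the values given above in both directions under either other pseudocount, no filter, each other scaling, no trend, a robust fit and a required 2-fold change. With a mean of at least 50, 709 were higher and 634 lower among 5614 tested. The replicate numbers are shared by the groups, but the labels do not say that they pair samples, and the replicate 1 minus 2 differences of the groups correlated at 0.442 across genes. With the replicate number as a block, 2845 were higher and 2876 lower. Leaving out 1 library in turn gave 69 to 271 higher and 137 to 365 lower genes, with the lone library of a group assumed to vary like the others, and 132 genes (24 higher and 108 lower) kept their call each time. Of 110 named genes with a call, 95 kept it under all settings that used every library and tested them, and 0 reversed under any setting. Named genes that kept the call without each library in turn were all listed at 0 in both libraries of 1 group. The values of that group then have no spread, so these calls are not the firmest results. Against 2 lists past the threshold, there were 5 without a filter, 7 with quantile normalization, 4 with the trimmed mean, a common total or the block, 4 to 7 without 1 library, 0 with an estimated correlation and, against no change rather than against other genes, 8 by fry. Oxidative phosphorylation genes turned lower past the threshold without myl7:EGFP+ replicate 1 (adjusted p = 0.0478) and higher past it without its replicate 2 (0.00990), and were not called without either tp1:EGFP+ library (0.115 and 0.178). Members of this list such as atp5po, named after its values were seen, were lower in replicate 1 of both groups. Its values were 402 and 2167 in myl7:EGFP+ and 518 and 2033 in tp1:EGFP+. Leaving out 1 myl7:EGFP+ library therefore sets a single replicate number against both, which moves such genes up or down. What changed the calls of other lists was not tested. Mean r within groups was 0.919 at a mean of at least 50, and mean r between groups was 0.683 with a pseudocount of 10 and 0.483 at a mean of at least 50. Genes at a value of at least 10 numbered 9882 and 8940 in myl7:EGFP+ and 9088 and 8569 in tp1:EGFP+. Count models were not run, since whole reads were not recovered, and camera has no robust form.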

Other observations

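The tests of a shared pool, of mural and endothelial cells and of annotated pathways were chosen after the results they bear on were seen. Camera over 122 annotated KEGG pathways found 0 at an adjusted p under the threshold, 7 at an unadjusted p under 0.05, and a smallest adjusted p of 0.562.

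Of 6058 genes at 50 or more in both libraries of a group, 271 were at 3 or less in both libraries of the other, 160 of them in tp1:EGFP+. Loss of transcripts in low-input amplification is argued against as the whole cause, since genes of 14 core cellular pathways showed the pattern at 0.151 times the rate of other genes of the same level (95% interval 0.041 to 0.387, 4 of 639 genes against 26.5 expected). A difference in expression between the cell groups would go with cell type markers showing it at 5.03 times that rate (95% interval 2.17 to 9.90, 8 of 42 genes). Other cells carried into a single sort would give this too, so the rate does not separate them from expression in cardiomyocytes. The 111 genes near 0 in myl7:EGFP+ limit an expression difference as their cause. That group marks cardiomyocytes in general, so reporter-active cells in it would have to be few. Whether both libraries of a group share one captured pool of RNA or cDNA cannot be told apart from this, because 0 core genes were split in this way between the libraries of a group against 9 to 12 between groups, which real group differences would give too. Over all genes, 1 was split within myl7:EGFP+ and 0 within tp1:EGFP+, against 461 to 514 between groups. Of 836 tested core genes, 163 (19.5%) were called, against 34.1% of all tested genes. Many calls thus fell on genes that every cell uses, and a difference between captured pools stays open as a part of their cause. The share of genes near 0 in the other group fell with level. For genes present in myl7:EGFP+ it was 6.96% at a mean of 50 to 100 and 0.299% at 800 to 1600. For genes present in tp1:EGFP+ it was 5.04% and 0% at these levels. Loss of transcripts would give this too, so loss as a part of the cause stays open. The pattern therefore stays a hypothesis about the sorted cells, and rbpja at 0 in Notch-reporter cells is a value to check in independent sorts.

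In both groups abundant genes were lower in replicate 1 than in replicate 2, by a median log2 of -0.95 in myl7:EGFP+ and -0.55 in tp1:EGFP+ for 434 genes with a mean of 800 to 3200. Collapsing of duplicate reads in the deeper libraries may explain this, since it would saturate short genes first, and the log2 ratio of replicate 1 to 2 of genes with a span under 5 kb differed by -1.29 from that of genes over 50 kb at a mean of 800 or more (95% interval -1.63 to -0.99). Loss of short transcripts in preparing the replicate 1 libraries stays open, because the same difference was -0.481 at a mean of 20 to 100 (95% interval -0.59 to -0.37). Collapse would act least at this low level, so it may not account for the whole difference. The spans are those of genes on the genome, not transcript lengths. No biological explanation was tested for this split.

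Mural markers were higher in tp1:EGFP+ and endothelial markers higher in myl7:EGFP+, but both set calls were lost with an estimated correlation (adjusted p = 0.787 for each). Loss of transcripts stays open for these lists. The rates of core and marker genes above covered only genes at 50 or more in both libraries of a group. The gene tie1 (53 and 56) reached that level. By contrast myh11a (60 and 48), pdgfrb (19 and 27), erg (44 and 28) and fli1a (89 and 44) did not. Smooth muscle cells in the tp1:EGFP+ sort would have had to pass its myl7:DsRed2-NLS gate, and stay open because 5 of 7 mural genes in no other list were higher within both replicate numbers, while rgs5b (438 and 1032 against 353 and 545) and cd248a (384 and 168 against 189 and 69) were lower without passing the test, and acta2, the most abundant mural gene but also in another list, had 128 and 134 against 1083 and 3022. Endothelial cells in the other sort would have had to pass its myl7:EGFP gate, and stay open because 16 of 20 endothelial genes in no other list were higher there, among them the most abundant, podxl, at 1141 and 843 against 402 and 340, while pecam1 and cldn5b, at low values, were called higher in tp1:EGFP+. A change in gene expression of the cardiomyocytes themselves was not separated from these.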
